A study of Drosophila melanogaster with 24 samples.

How the data were processed

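The deposited table of each of the 24 arrays held 1 signal value per probe set, and the unit given by the authors is intensity. The software that made these values is not given in the sources used here. The values were linear. Their 2%-trimmed mean was 150.004 to 150.005 on every array, so the authors' scaling to a common mean was kept under a rule that allowed a ratio of 1.05 between arrays. The array medians ran from 9.82 to 20.9, a ratio of 2.12. Values were turned into log2(signal + 32), so the size of a change from or to a signal under 32 depends on this offset. Of 18952 probe sets, 183 for spiked or control transcripts were left out and 18769 were tested, with no filter on low values. Of the tested probe sets, 13647 named a single gene, 402 named several and 4720 named none. They stood for 11982 genes, and gene positions came from the RefSeq table of the fly genome (Release 6 plus ISO1 MT).

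The labels gave 8 mixes of 2 cell populations, 45 minutes of mixing, and 2 independent samples pooled for each replicate. A mix is written here as both populations joined by a stroke, for example S2/S2-Dl. Dl stands for a line with Delta and DlDI for a line with Delta lacking its intracellular domain. NFull and NDCterm are read here as lines with forms of Notch, the receptor of Delta, since the labels do not spell these names out. The array type fits Drosophila, and S2 is a hemocyte-like line of this fly. The source field named epidermal tissue of late embryos, and the titles named S2 cells. The titles and the design text were followed.

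On 5 occasions a pair of arrays bore the same title apart from a closing 1 or 2. Before the data were examined it was fixed that such a pair would be averaged only if its arrays differed less than separate replicates do, and otherwise left out. Over the upper part of the probe sets by mean, the SD of the log2 difference between separate replicates of a mix was 0.213 to 0.486 in 9 reference pairs, and Delta differed by at most 0.483. Only S2-NFull/S2-DlDI replicate 2 passed (SD 0.126, Delta 0.288). S2-NDCterm/S2-Dl replicate 2 (0.380, Delta 7.96), S2-NFull/S2 replicate 1 (0.339, Delta 0.385), S2-NFull/S2-DlDI replicate 1 (0.373, Delta 6.03) and replicate 3 (0.383, Delta 8.36) did not, and their 8 arrays were left out of every main result. No sample was moved to another mix because of its values. Of the 24 pairs of mix and replicate number, 5 held 2 arrays, 14 held 1 and 5 held none.

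The fit then rested on 15 samples: 3 of S2/S2, 3 of S2/S2-Dl, 2 each of S2/S2-DlDI, S2/S2-NDCterm and S2-NDCterm/S2-Dl, and 1 each of S2-NFull/S2, S2-NFull/S2-Dl and S2-NFull/S2-DlDI, the last from 2 averaged arrays. With limma, 1 linear model covered the 8 mixes and 13 contrasts, with a moderated spread and a mean trend (7 residual degrees of freedom, 6.26 from the prior). A probe set was called at a Benjamini-Hochberg adjusted p below 0.05 within its contrast. Every adjusted p of a gene comes from limma. A mix with 1 sample has no spread of its own and borrows that of the others, which assumes that it varies as they do. No probe set named Notch alone, so Notch is not analysed here.

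A gene was named by a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls per comparison among called genes whose higher mean signal reached 9.75, the median over all probe sets, and whose samples did not overlap between the mixes. It also took Delta, the E(spl) genes and every called member of 29 gene lists, and where under 5 genes passed, the 5 smallest p values. The probe set with the highest mean stood for a gene with several. The lists covered pathways, stress responses, cell machinery and cell type markers, and were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry. Their p values were adjusted over the lists of a comparison. A count adjusted over the list alone is also given where it differs.

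The pairing of replicate numbers was checked by correlating the residuals of samples with the same number. For S2/S2 and S2/S2-Dl these were 0.665, 0.421 and 0.523, so the result with replicate number as a block is given beside that comparison. Pairs with different numbers had -0.43 to 0.000183. Residuals cancel within a mix, so positive values at the same number force lower ones at different numbers, and this contrast adds little. The other pairs of mixes shared 2 numbers at most. Alternatives fixed before the data were examined were quantile normalization, offsets of 8 and 128, a filter on low values, no mean trend, 5 ways of treating the arrays of a shared title, the replicate block, a fit on the compared mixes only and leaving out each sample in turn. A sample that was the only 1 of its mix could not be left out.

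The procedure was tested on simulated data with 18769 probe sets, 200 of them changed, in 10 draws. At a log2 change of 2 it recovered 98.4% for S2/S2-Dl against S2/S2 (4.70% of the calls were false), 97.4% for S2-NDCterm/S2-Dl against S2/S2-NDCterm (5.30%) and 87.6% for S2-NFull/S2-Dl against S2-NFull/S2 (4.89%). At a log2 change of 1 these were 77.2%, 60.4% and 14.8%. The changed probe sets were drawn only from the upper part by mean. Simulated noise was independent between samples, with the same spread in every mix and no replicate effect. These shares therefore do not test the assumption made for a mix with 1 sample. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.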

Results

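The series asked which genes answer when cells with a form of Notch meet cells with Delta, and whether the intracellular part of Delta matters for that answer. It set 8 mixes of S2 populations against each other after 45 minutes. RNA came from both populations of a mix together, so a gene that a line makes by itself moves the signal in the same way as a gene that answers to contact. In S2/S2, markers of plasmatocytes, the phagocytic blood cells, had a median signal of 224, with 7 of 11 above 100, among them srp (599.7), ush (1070.0) and Pxn (622). Hml, another blood cell marker, was at 8.79. Epidermal markers had a median of 9.05, with 0 of 11 above 100. Medians were 47.2 for crystal cell and lamellocyte markers, 6.20 for neurons, 102 for glia, 3.58 for muscle, 7.33 for fat body and 16.8 for the germline. Single members stood higher, such as elav (206), loco (945) and aub (634).

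Delta, the ligand, and ry, which encodes xanthine dehydrogenase, separated the mixes with Dl cells from the rest. Delta signal was 12309 ± 1074 in S2/S2-Dl (n = 3), 11409.5 ± 271 in S2-NDCterm/S2-Dl (n = 2) and 12132 in S2-NFull/S2-Dl (n = 1), against 34.0 ± 11.7 in S2/S2 (n = 3). It was 13.6 ± 2.38 in S2/S2-DlDI (n = 2). The Delta probe set may lie outside the part that the DlDI line carries, so this low value checks nothing there. Among the left-out arrays, array 1 of S2-NFull/S2-DlDI replicates 1 and 3 had Delta signals of 12295 and 11031, and array 2 of S2-NDCterm/S2-Dl replicate 2 had 13.9.

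**Figure D1:**
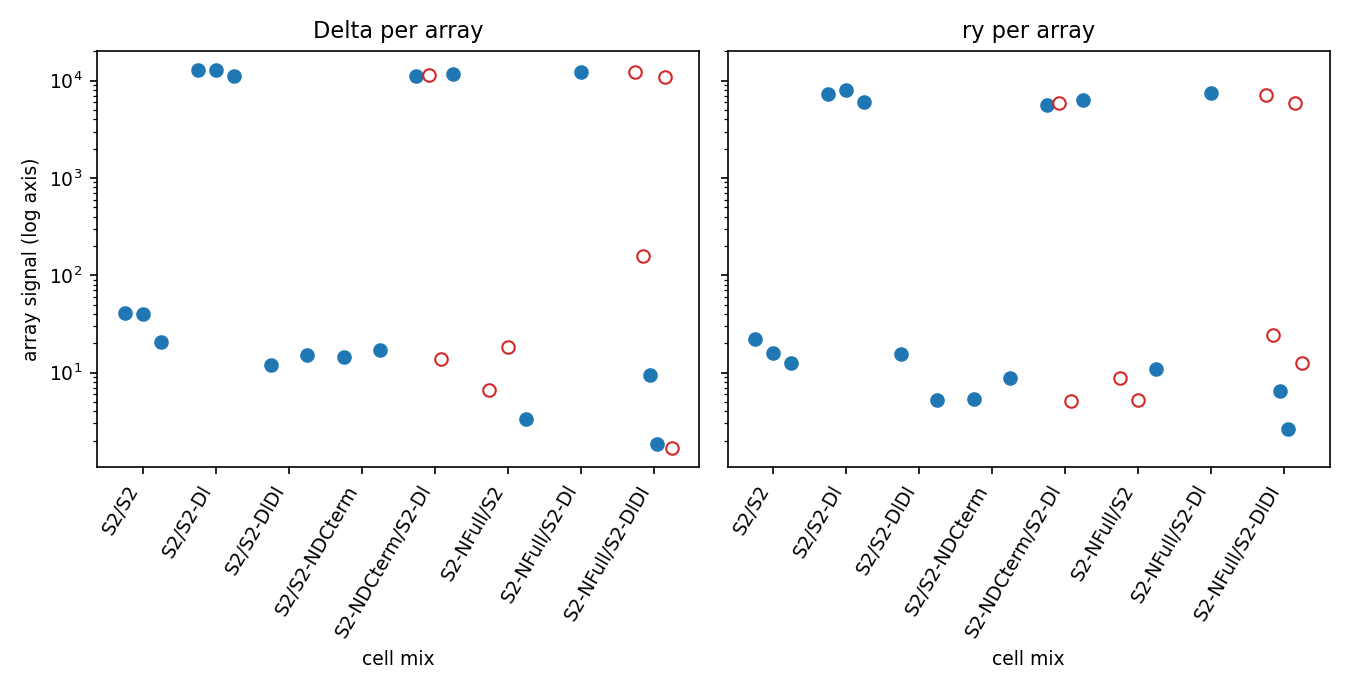
Signal of Delta and ry on each array, by mix, on a log axis. Filled blue points are arrays used in the fit and open red points are arrays left out because the arrays of a shared title differed.

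Against their partner without Dl cells, limma called 208 probe sets higher and 37 lower in S2/S2-Dl, 73 and 19 in S2-NDCterm/S2-Dl, and 33 and 22 in S2-NFull/S2-Dl. DlDI cells gave 14 higher and 0 lower beside S2 cells, and 3 and 1 beside NFull cells. The mixes differ in sample number, so these counts do not rank the size of the answers.

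**Figure D2:**
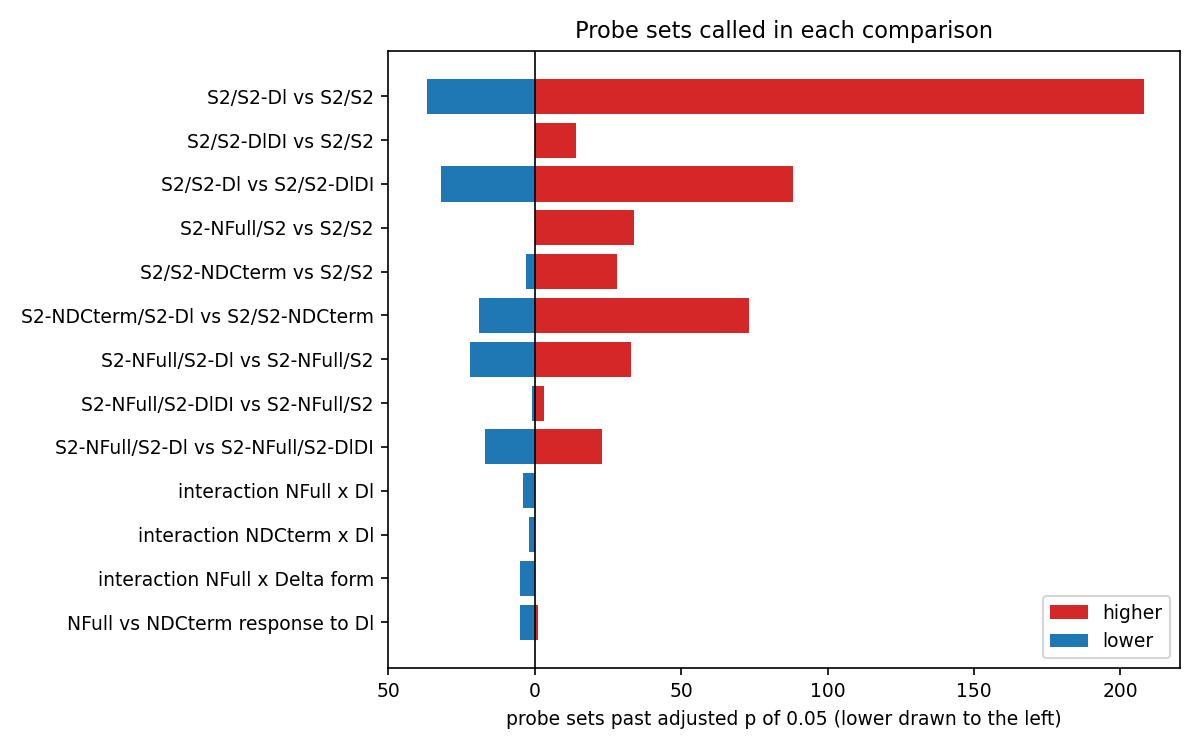
Number of probe sets called higher (bars to the right) and lower (bars to the left) in each comparison at an adjusted p below 0.05.

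Does adding Delta cells to plain S2 cells change expression? In S2/S2-Dl, besides Delta (log2 change 7.56 ± 0.13 SE, adjusted p = 5.1e-13) and ry (7.18, 8.79e-13), the largest rises among named genes were RpS5b, a ribosomal protein paralogue (3.48, 1871 ± 573 against 155 ± 96.1), TpnC4, a troponin C of muscle (3.45, 389 against 6.25 ± 7.47), and CG12493 (3.44). l(3)87Df, a direct neighbour of ry on the chromosome, rose by 3.31 (8207 ± 941 against 814 ± 212). Ten-m, a teneurin of the cell surface, rose by 2.38 (921 ± 102 against 152 ± 32.6), and dpr19, an immunoglobulin domain gene, by 2.33. CG4829, CG42613, CG6357 and CG5568 rose by 2.27 to 2.55. TpnC4 (3.87), CG5568 (2.22) and CG12493 (1.93) also rose in S2-NFull/S2 (n = 1), which holds no Delta cells. Falls were smaller: Oatp58Dc, an organic anion transporter, went from 1313 ± 223 to 635 ± 135 (log2 change -1.02, adjusted p = 0.0086), CG7900 from 1789 ± 215 to 987 ± 129 (-0.84), and Fer2LCH, the ferritin light chain, from 505 ± 32.4 to 287 ± 54.1 (-0.76). CG3251 (-0.88), Swim (-0.83), CG11929 (-0.81) and CG11699 (-0.78) fell as well. The mix still held plain S2 cells, whose RNA limits how far a signal can fall. Falls and rises are therefore not comparable in size here. The same limit applies to S2/S2-DlDI, S2-NFull/S2 and S2/S2-NDCterm below.

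None of the 13 measured E(spl) complex and Bearded family genes, the classical targets of Notch, passed in S2/S2-Dl. Their camera adjusted p was 0.708, and the E(spl) genes named here lay between -0.23 and 0.23. Among other known Notch targets 1 of 12 passed (2 adjusted over the list alone): ct, a homeodomain factor, at 0.78. PCNA, the sliding clamp of DNA replication, rose by 1.45 (3676 ± 576 against 1321 ± 143), the only called member of 15 cell cycle genes (3 adjusted over the list alone; camera adjusted p = 0.0134, adjusted p = 0.662 with an estimated correlation). sty, an antagonist of EGFR signalling, rose by 1.04 (1610 ± 175 against 767 ± 99.0), the only 1 of 6 in its list, and ovo, a transcription factor of epidermis and germline, by 1.61, the only 1 of 11 epidermal markers. In the JNK and wound list 10 of 10 genes had a positive change, with bsk, the JNK kinase itself, the only call (0.44; camera adjusted p = 0.0287, adjusted p = 0.608 with an estimated correlation). In the extracellular matrix list 0 of 10 passed over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0287, adjusted p = 0.48 with an estimated correlation). Fas1 (0.63), Prosbeta2 (0.68) and crq (0.70), a scavenger receptor of blood cells, were the only calls of 15 adhesion genes, 41 proteasome genes and 11 plasmatocyte markers (2 adjusted over the list alone in each of these 3 lists).

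The 245 calls belonged to 176 genes higher and 30 lower, with 29 probe sets that name no gene. Without S2/S2-Dl replicate 1 or 2 there were 130 or 93 calls, and without replicate 2 the adjusted p was 0.0594 for ct, 0.239 for bsk, 0.19 for Fas1, 0.141 for Prosbeta2 and 0.158 for crq. With replicate number as a block there were 540 calls (368 higher, 172 lower), which held all 245. In that fit glycolysis was lower as a list (camera adjusted p = 0.00929, against 0.127 without the block, and adjusted p = 0.792 with an estimated correlation). The ratio of 3' to 5' Gapdh signal also differed, at 1.95, 1.74 and 2.82 in S2/S2-Dl replicates 1 to 3 and 2.71, 2.77 and 2.97 in S2/S2. Its part in this was not tested.

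Does Delta without its intracellular domain do the same? In S2/S2-DlDI, CG6067 rose most among named genes, from 1.42 ± 1.27 to 252 ± 67.2 (log2 change 3.07, adjusted p = 1.5e-06, n = 3 and 2). It was followed by GILT3, a lysosomal thiol reductase (1.82), Or82a, an odorant receptor (1.58), su(r), an enzyme of pyrimidine breakdown (1.58), and CG14273 (1.47, 1693 ± 341 against 588 ± 68.2). Slik, a kinase of the cell cortex, rose from 405 ± 24.1 to 790 ± 16.0 (0.91) and wgn, a receptor of the TNF family, from 718 ± 92.4 to 1366 ± 144 (0.90). Delta was at -0.52 (adjusted p = 0.451). No E(spl) gene passed (0 of 13), and no gene fell past the test.

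Several lists shifted slightly in S2/S2-DlDI without a called member over all genes. EGFR/Ras (6 of 6 positive, 2 called adjusted over the list alone), actin and adhesion (13 of 15, 1 called alone) and extracellular matrix (7 of 10, 3 called alone) lay higher, each with a camera adjusted p of 0.00138 (adjusted p = 0.101 with an estimated correlation). Ribosomal proteins lay lower, with 0 of 37 positive (camera adjusted p = 0.0153, adjusted p = 0.686 with an estimated correlation), as did glycolysis with 0 of 9 positive (0.0179, and adjusted p = 0.6 with an estimated correlation). With replicate number as a block neither list passed (camera adjusted p = 0.179 for both). The call of CG6067 alone, of 9 named genes, held whichever sample was left out. Without DlDI replicate 2, 4 probe sets were called in place of 14, and the adjusted p was 0.319 for GILT3, 0.177 for CG14273 and 0.91 for su(r). Without replicate 3, 6 were called, with 0.186 for Slik and 0.595 for wgn.

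The direct test of S2/S2-Dl against S2/S2-DlDI called 88 probe sets higher and 32 lower. Residuals of the same number correlated at 0.321 and 0.335 between these mixes, and with replicate number as a block 142 were higher and 77 lower. Delta (8.08), ry (7.40), RpS5b (4.40), l(3)87Df (3.79), TpnC4 (3.53), Ten-m (2.79), CG10859 (2.59), PCNA (1.21, adjusted p = 0.00128) and ovo (1.53) were higher with the full Delta. Higher with DlDI were CG6067 (252 ± 67.2 against 0.852 ± 0.478, log2 difference -3.09), Esyt2, a lipid-transfer protein of membrane contacts (725 ± 101 against 112 ± 59.3, -2.47), GILT3 (-2.19), Or82a (-1.96), Oxp (-1.67) and Oatp58Dc (1889 ± 80.1 against 635 ± 135, -1.55). Tsp42Ea, a tetraspanin (447 ± 46.3 against 926 ± 66.4), and kst, the heavy beta spectrin (-0.97), were also lower with the full Delta. Of 37 ribosomal proteins 34 were positive, but only RpS5b was called (camera adjusted p = 0.000815, adjusted p = 0.939 with an estimated correlation). Without DlDI replicate 2 or 3 there were 52 or 46 calls, and without replicate 2 the adjusted p was 0.145 for Tsp42Ea and 0.396 for kst.

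Does a Notch line alter expression before it meets a ligand? In S2-NFull/S2 (n = 1) aos, a secreted inhibitor of the EGF receptor, stood at 1087 against 49.0 ± 33.1 in S2/S2 (log2 change 3.88 ± 0.46 SE, adjusted p = 0.00164). TpnC4 rose by 3.87 (520 against 6.25), CG14932 by 2.87, RpS10a, a ribosomal protein paralogue, by 2.60 (556 against 66.4 ± 22.1) and DptB, an antibacterial peptide, by 1.72 (89.7 against 4.88). E(spl)mbeta-HLH and E(spl)m3-HLH, repressors of the basic helix-loop-helix class, rose by 1.17 (703 against 296 ± 5.19) and 1.60 (686 against 213 ± 73.5; adjusted p = 0.0394, and 0.0622 after quantile normalization). These were 2 of 13 in the E(spl) list (3 adjusted over the list alone; camera adjusted p = 0.0335, adjusted p = 0.314 with an estimated correlation). In the EGFR/Ras list aos and sty (1.54, 2281 against 767 ± 99.0) were 2 of 6 (3 adjusted over the list alone; camera adjusted p = 0.00387, adjusted p = 0.314 with an estimated correlation). ovo rose by 1.51. TpnC4, sty and ovo, with CG5568 (2.22) and CG12493 (1.93), had also risen in S2/S2-Dl. A rise of these genes was thus not particular to mixes with Delta cells. No probe set fell past the test, and 34 rose. The NFull mix rests on replicate 3 alone, so a difference of that sample cannot be told from a difference of the line. With the arrays of every shared title averaged, 174 were called, among them E(spl)mbeta-HLH and E(spl)m3-HLH but not DptB. That setting adds replicate 1 of this mix, but also the left-out arrays of other mixes, which change the shared spread. In a fit on these 2 mixes only neither E(spl) gene passed.

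In S2/S2-NDCterm (n = 2) the largest rise of a named gene was E(spl)m3-HLH itself, from 213 ± 73.5 to 1277 ± 52.0 (log2 change 2.47 ± 0.22 SE, adjusted p = 0.000288). E(spl)mbeta-HLH rose by 1.16 (706 ± 113 against 296 ± 5.19). E(spl)m2-BFM was at 0.80 (adjusted p = 0.215), E(spl)mdelta-HLH at 0.62 (0.258) and E(spl)malpha-BFM at 0.44 (0.528). Of 13 genes of the list 2 passed (4 adjusted over the list alone; camera adjusted p = 0.000621, adjusted p = 0.0827 with an estimated correlation; fry 0.011). The median change of the list was -0.00373 and its mean 0.382, so the shift came from few members. CG15695 (2.45), CG4927 (2.23, adjusted p = 0.000705), CG4259 (1.94), NimC4, a receptor for dying cells (1.52), and RhoL, a small GTPase of blood cells (1.38), rose too. mRpL14, a mitochondrial ribosomal protein, fell from 1600.3 ± 182 to 876 ± 9.34 (-0.84).

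**Figure D3:**
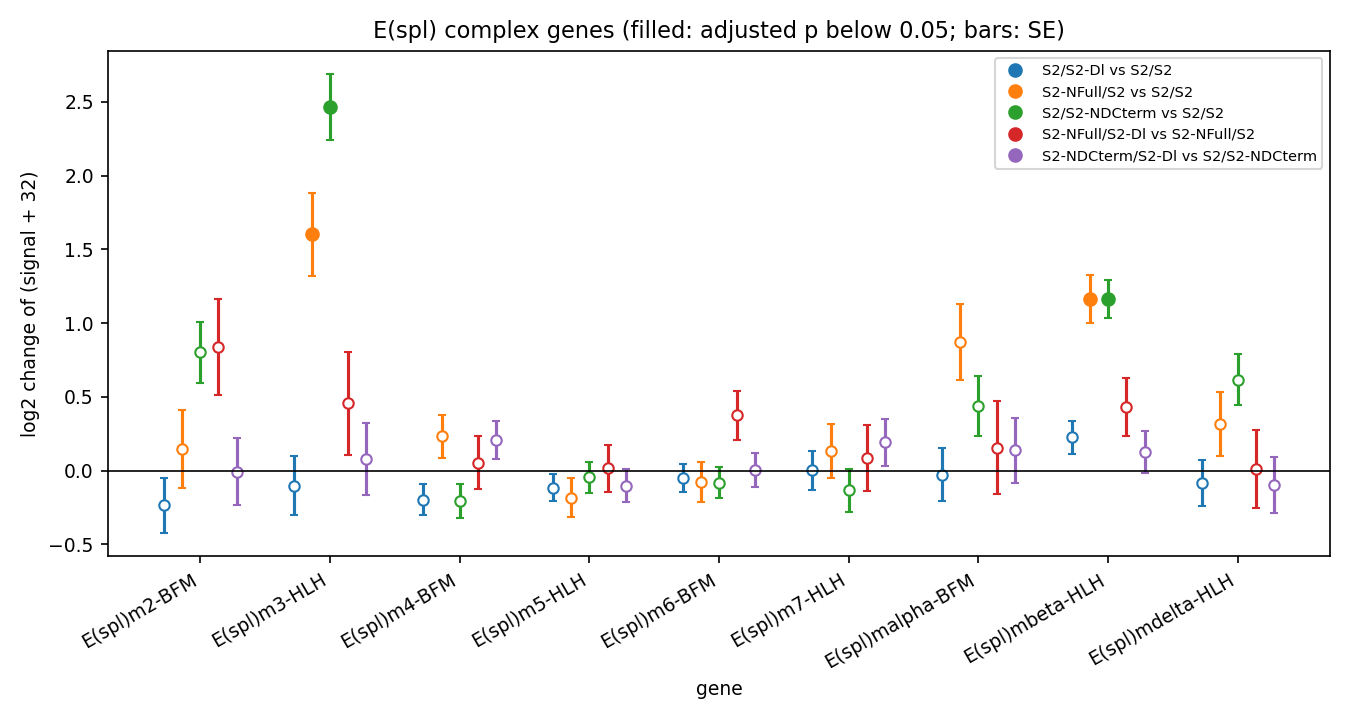
Log2 change with SE of the E(spl) complex genes in each comparison. Filled points had an adjusted p below 0.05.

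Glycolytic enzymes lay lower in S2/S2-NDCterm, with 0 of 9 positive, 0 called over all genes and 5 lower adjusted over the list alone (camera adjusted p = 0.000191, adjusted p = 0.289 with an estimated correlation). With replicate number as a block 6 of the 9 were called lower (camera adjusted p = 4.86e-11, adjusted p = 0.168 with an estimated correlation), and the comparison had 143 probe sets higher and 150 lower in place of 28 and 3. Residuals of the same number correlated at only 0.0693 and 0.0593 between these mixes, so the block has little basis here. It left 5 residual degrees of freedom. The ratio of 3' to 5' Gapdh signal was 2.41 and 1.87 in S2/S2-NDCterm and 2.71, 2.77 and 2.97 in S2/S2, and S2/S2 replicate 2 had a median signal of 20.9 against 11.6 and 11.2 in the other replicates. Immune effectors, with 11 of 14 positive, and the JNK and wound list, with 7 of 10, lay higher, each with a camera adjusted p of 0.000404 (adjusted p = 0.248 with an estimated correlation). Plasmatocyte markers lay higher with 8 of 11 positive (0.00429, and adjusted p = 0.0827 with an estimated correlation). Of 31 calls, 6 were left without NDCterm replicate 1 and 5 without replicate 3, and there were 71 without S2/S2 replicate 3. Among 15 named genes only E(spl)m3-HLH and CG4927 held whichever sample was left out, and E(spl)mbeta-HLH had an adjusted p of 0.078 without replicate 1, while that of NimC4 was 0.457, of RhoL 0.479 and of mRpL14 0.455 without replicate 3.

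When NDCterm cells were mixed with Delta cells, nearly all genes called in S2/S2-Dl changed in the same direction, and a part of them passed. In S2-NDCterm/S2-Dl against S2/S2-NDCterm (n = 2 each), Delta rose by 7.90, ry by 7.27 (5989 ± 477 against 7.05 ± 2.49), RpS5b by 4.59, CG12493 by 3.41, l(3)87Df by 3.39, TpnC4 by 3.25, Ten-m by 2.14 and ovo by 1.97 (adjusted p = 0.000546). PCNA rose by 1.28 (3775 ± 295 against 1539 ± 80.4) and sty by 0.83. Falls reached -2.19 in CG2256 (142 ± 42.1 to 5.93 ± 7.41), -1.43 in HP6, a chromatin protein (1527 ± 32.6 to 547 ± 64.9), -1.27 in Swim, a secreted Wingless-binding protein, and -1.22 in dmGlut, a glutamate transporter. The E(spl) genes, already high in E(spl)m3-HLH and E(spl)mbeta-HLH, stayed between -0.10 and 0.21 and none of 13 passed (camera adjusted p = 0.991). The cell cycle list lay higher with 1 of 15 called (camera adjusted p = 0.0259, adjusted p = 0.991 with an estimated correlation).

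Of 60 genes higher here and 176 higher in S2/S2-Dl, which share no array, 54 were the same, where independent calls would give 0.881. Of 18 and 30 lower genes 4 were the same (0.0451 expected). Of the 176 higher and 30 lower genes of S2/S2-Dl, 175 and 30 changed in the same direction here, called or not. Across 11982 genes the changes had a correlation of 0.654, though genes do not vary independently. Both comparisons add the same Dl line, whose own genes rise in both, and both use the same spread per probe set. Overlap above that of independent calls was therefore built in and is no evidence of a shared answer to contact. Without S2-NDCterm/S2-Dl replicate 1 or 3 there were 35 or 16 calls, and without S2/S2-NDCterm replicate 1 or 3 there were 19 or 26, in place of 92. Without S2-NDCterm/S2-Dl replicate 3 the adjusted p was 0.0896 for PCNA and Swim, 0.382 for sty and 0.254 for HP6, and without S2/S2-NDCterm replicate 1 it was 0.282 for dmGlut.

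**Figure D4:**
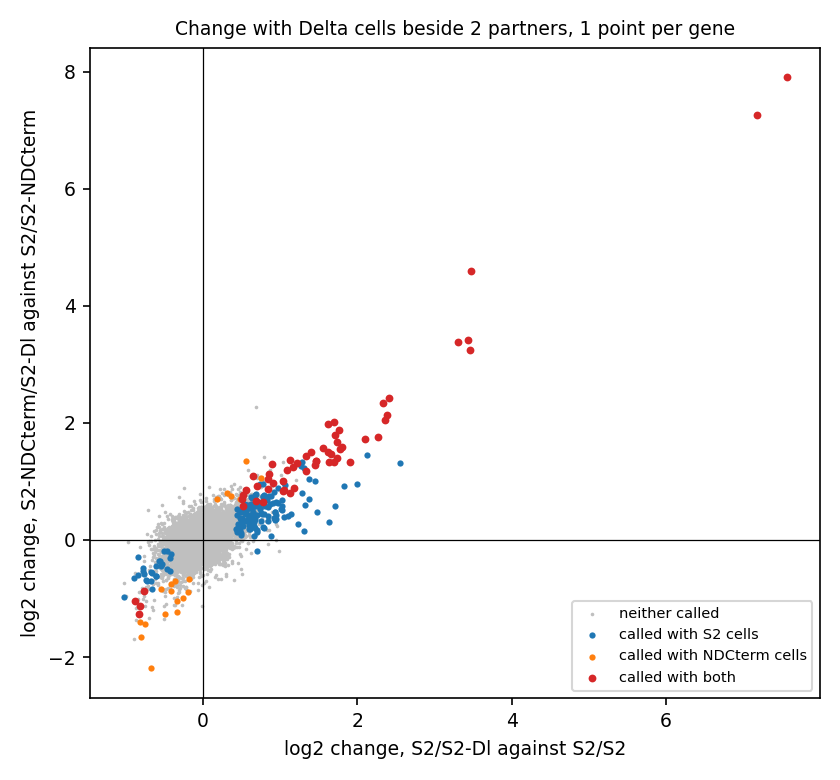
Log2 change with Delta cells beside NDCterm cells against the change beside S2 cells, 1 point per gene.

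Large falls were seen when Delta cells took the place of plain S2 cells beside NFull cells. In S2-NFull/S2-Dl against S2-NFull/S2 (n = 1 each), CG7900 went from 1057 to 17.3 (log2 change -4.47 ± 0.21 SE, adjusted p = 5.21e-08), CG15784 from 7368 to 328 (-4.36) and Oatp58Dc from 785 to 10.4 (-4.27). CG3168, a putative transporter (-2.41), CG2256 (-2.33), Fer2LCH (399.6 to 62.1, -2.20), HP6 (-2.04) and Swim (-1.97) fell as well. A gene that plain S2 cells make and Delta cells lack falls here without any contact. The signal of S2-NFull/S2 plus that of S2/S2-Dl minus that of S2/S2 gives 254.7 for CG7900, 106.8 for Oatp58Dc and 4773 for CG15784. Much of the fall of CG7900 and Oatp58Dc may thus need no contact. Rises again included Delta (8.43), ry (7.44), RpS5b (4.17), l(3)87Df (3.49), CG6357 (2.95), dpr19 (2.78) and PCNA (1.59, 4599 against 1504). All 13 E(spl) and Bearded genes had a positive change but none passed (camera adjusted p = 0.134): E(spl)m2-BFM was at 0.84 (adjusted p = 0.431), E(spl)m3-HLH at 0.46 (0.774) and E(spl)mbeta-HLH at 0.43 (0.516). Of 28 genes higher here, 26 were also higher in S2/S2-Dl (0.411 expected), and of 20 lower genes 8 were also lower there (0.0501 expected). This comparison and S2/S2-Dl add the same Dl line and use the same spread, so such overlap was built in. The NFull samples compared bear replicate numbers 2 and 3, and that difference can be taken out only as far as the other mixes estimate it. Low signals also stood higher in S2-NFull/S2-Dl (10th percentile 1.56, median 14.2) than in S2-NFull/S2 replicate 3 (1.01 and 10.9). The median change over all probe sets was 0.033. Whether this shift made the E(spl) and Bearded changes positive was not tested. With replicate number as a block there were 52 calls, 37 of them among these 55. Of the named genes only CG7900 and CG34330 kept their call in every alternative. Delta, ry, CG15784 and Oatp58Dc were not called with every array as its own sample or with the first array only. Both settings place array 1 of S2-NFull/S2-DlDI replicates 1 and 3, with Delta signals of 12295 and 11031, in that mix. The mixes share a spread, so these arrays bear on this comparison as well.

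The truncated Delta was then set beside NFull cells. In S2-NFull/S2-DlDI against S2-NFull/S2, CG6067 rose from 0.346 to 299.7 (log2 change 3.36, adjusted p = 0.000116) and CG7900 fell from 1057 to 241 (adjusted p = 0.00116). CG3625 (-1.37, 0.0768), CG7878 (-1.02, 0.128) and Or82a (1.81, 0.128) had the next smallest p values and did not pass. E(spl)m2-BFM was at 0.95 and E(spl)mbeta-HLH at 0.74 (adjusted p = 0.845), with 0 of 13 called (1 adjusted over the list alone). Here too the samples bear replicate numbers 2 and 3, and 1 sample stands for each mix. DlDI cells took the place of plain S2 cells, so the fall of CG7900 need not come from contact. With the block 9 probe sets were called, which held all 4. There were 17 with all arrays of a shared title averaged, 25 with the second array only, 19 with the first only and 81 with every array as its own sample, and CG6067 did not pass in the last 2 of these.

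S2-NFull/S2-Dl and S2-NFull/S2-DlDI share replicate number 2. Between them Oatp58Dc (10.4 against 1297, -4.97), CG15784 (328 against 6545, -4.19), CG6067 (-3.33), CG3168 (-2.78), CG7900 (17.3 against 241, -2.47) and Fer2LCH (-2.24) were lower with the full Delta, as was bves, a membrane protein of muscle (-1.48). Delta (8.35), ry (7.67), l(3)87Df (3.98), RpS5b (3.93), CG12493 (2.49) and PCNA (4599 against 1607, adjusted p = 0.0165) were higher, among 23 probe sets higher and 17 lower. No E(spl) gene of 13 passed (camera adjusted p = 0.977). A single sample per mix supplied each side. Averaging, every array and the first array only put array 1 of S2-NFull/S2-DlDI replicates 1 and 3 on the DlDI side. The Delta signals there were 12295 and 11031, so these settings dilute the difference between the Delta forms. None of the 25 named genes kept its call in every alternative: there were 5 calls with all arrays of a shared title averaged, 4 with the first array only, 105 with the second only and 71 with the block.

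The difference of differences was then tested, since a gene called in one mix and not in another need not differ between them. With NFull in place of S2, the change seen with Delta cells was lower for CG15784 (-3.73, adjusted p = 0.0142), CG7900 (-3.63, 1.86e-05) and Oatp58Dc (-3.25, 0.00265). It was also lower for 1 probe set of Imp, an RNA-binding protein (-2.28, 0.0114), though the probe set that stands for Imp was not called. TpnC4 (-2.34, 0.0708) and Fer2LCH (-1.43, 0.128) did not pass. With replicate number as a block 7 probe sets were called in place of 4, and TpnC4 was among them (-2.59, adjusted p = 0.0195). All 13 E(spl) and Bearded genes had a positive difference, with 0 called (camera adjusted p = 0.0114, adjusted p = 0.313 with an estimated correlation). The median difference over all probe sets was 0.0758 here, and many E(spl) genes had signals under 32. Whether a shared upward shift made these signs was not tested. The Imp probe set rose with Delta cells beside both partners (3.70 beside S2, 1.42 beside NFull). The difference between the full and the truncated Delta was lower beside NFull than beside S2 for Oatp58Dc (-3.42), CG15784 (-3.40), TpnC4 (-2.66) and CG7900 (-2.15). Lower refers to log2 values. TpnC4 signal rose with the full Delta from 0.7475 and 7.434 to at least 293.7 beside S2, and from 614.9 and 631.8 to 1162 beside NFull. Of 5 samples left out in turn, 3 ended the call of CG15784 (S2/S2-Dl replicate 1 and both DlDI replicates) and 4 that of TpnC4 (these and S2/S2-Dl replicate 2). The adjusted p reached 0.25 for CG15784 without DlDI replicate 2 and 0.159 for TpnC4 without replicate 3, with 3 of 5 probe sets called in each case. With all arrays of a shared title averaged, only CG7900 kept its call against S2 (adjusted p = 0.00371), while CG15784 (0.207) and Oatp58Dc (0.296) did not.

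With NDCterm in place of S2 no named gene differed in its change with Delta cells. CG2256 had the smallest p (-1.52, adjusted p = 0.669), and limma called 2 probe sets that name no gene, with 650 at an unadjusted p under 0.05. Without S2/S2 replicate 1 there were 4, and without any other sample 1 or 2. NFull against NDCterm, by contrast, differed in CG7900 (-3.87, 8.56e-06), CG15784 (-3.82, 0.0166) and Oatp58Dc (-3.29, 0.003). The call of CG15784 was lost on leaving out any 1 of the 4 samples of the NDCterm mixes (adjusted p = 0.124 without S2/S2-NDCterm replicate 1), and without S2-NDCterm/S2-Dl replicate 3 there were 3 calls in place of 6. Taking away called genes in the way the series design sets out left 15 of 55 probe sets for NFull with Delta, 23 of 92 for NDCterm with Delta, 238 of 245 for Delta alone and 9 of 40 for NFull with the 2 Delta forms. Such a subtraction is not a test of a difference.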

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

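All tests of explanations in this part were chosen after the results were seen. Of 8 outlier checks within mixes, 2 picked out array 2 of S2-NDCterm/S2-Dl replicate 2, where Delta was 13.9 and ry 5.15, against Delta signals of 11218 to 11601 on the other arrays of that mix. Such a check picks out about 1 group in 20 by chance alone. Among the arrays left out of the fit, S2-NFull/S2-DlDI replicate 1 had a Delta signal of 12295 and a ry signal of 7100.5 on array 1 and of 156 and 24.3 on array 2, and replicate 3 had 11031 and 5836 on array 1. S2/S2 had Delta signals of 20.4 to 41.3 and ry signals of 12.4 to 22.3, so these values of the S2-NFull/S2-DlDI arrays lay above plain S2 cells, while array 2 of replicate 3 had a Delta signal of 1.67.

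Arrays that share a title should hold the same RNA. Noise of a repeated hybridization was excluded for the 3 pairs that differ in Delta, since the smallest of these differences was 6.03 on the log2 scale against 0.483 at most between separate replicates. For S2-NFull/S2 replicate 1 it stayed open, because the SD of 0.339 lay within that of separate replicates. A mislabelled sample may explain the others: array 2 of S2-NDCterm/S2-Dl replicate 2 lay nearer to S2/S2-NDCterm replicate 1 than to its own mix by an SD of 0.152 (0.206 against 0.357), and array 1 of S2-NFull/S2-DlDI replicates 1 and 3 lay nearer to S2-NFull/S2-Dl replicate 2 than to the 4 other arrays of their own mix by 0.119 or more. The numbers without an array are S2/S2-NDCterm replicate 2, S2-NFull/S2-Dl replicates 1 and 3, S2/S2-DlDI replicate 1 and S2-NFull/S2 replicate 2, but nothing here proves which RNA an array held, and no array was moved.

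The change with Delta cells differed between mixes for 4 named genes in the test of the difference. Against S2 the differences were -3.73 for CG15784, -3.63 for CG7900 and -3.25 for Oatp58Dc. Against NDCterm they were -3.82, -3.87 and -3.29. Between the Delta forms they were -3.40, -2.15 and -3.42, and -2.66 for TpnC4. The call of CG15784 against NDCterm was lost on leaving out any 1 of 4 samples, and between the Delta forms those of CG15784 and TpnC4 were lost for 3 and 4 of 5.

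A log2 difference of this kind also arises if the RNA of the mixed lines merely adds up, because a sum is not a product. Adding up remains possible for TpnC4, whose signal of 1162 lay 0.726 SE above the sum of 1008, within the limit of 2 SE. For CG7900 (17.3 against a sum of 254.7, -1.43 SE) and Oatp58Dc (-0.556 SE) the check cannot decide. Their SE of 165.8 and 173.4 was so large beside sums of 254.7 and 106.8 that no signal, however low, could have passed the limit. CG15784 (328 against a sum of 4773, -2.37 SE) and the Imp probe set (2.19 SE) lay beyond the limit with S2 as the reference, but within it for the 2 Delta forms (-1.48 and 0.97 SE). For CG15784 no fall could pass the limit between the Delta forms either, with an SE of 1928 for a sum of 3180. Adding up so stayed open for CG15784 and the Imp probe set as well. The genes were first tested as 2 sets, both beyond the limit, with Imp the farthest of 1 set and CG15784 the other, and were then split gene by gene at the same limit after these values were seen. With replicate number as a block 5 probe sets were still called, but this cannot exclude a difference between replicate numbers as the cause. The NFull mixes have 1 sample each, so the block took their shift from other mixes. That shift was not shared by all mixes. Residuals of the same number correlated at 0.421 to 0.665 for S2/S2 with S2/S2-Dl, but at 0.0693 and 0.0593 for S2/S2 with S2/S2-NDCterm.

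ry and its neighbour l(3)87Df rose with Delta cells. A fragment around ry carried in the Delta line, as a marker on its vector might be, is consistent with 0 of the 15 other measured genes within 12 places on each side being called higher (log2 changes of -0.40 to 0.13), although several of these lay near the floor of the signal. Signalling that needs an added Notch form was excluded as the cause, because ry changed by 7.18 with no Notch line in the mix.

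For the calls in S2/S2-Dl against S2/S2, 10 splits of the 6 samples exist and 1, the real one, gave as many as 245, while the highest other gave 4. So few splits cannot give a share below 0.05. They also exchanged samples without regard to the replicate numbers that S2/S2 and S2/S2-Dl share, in the fit without the block.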

How the results depend on the processing

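No test of a cause was run for the changes below, and the cause was not tested unless stated. No called result of a named gene reversed its direction. The glycolysis list in S2-NFull/S2-DlDI against S2-NFull/S2, which did not pass in the main result (camera adjusted p = 0.906), was higher with the block (0.0447) and lower with every array as its own sample (0.00269) or all averaged (0.00586), and none of these passed with an estimated correlation (adjusted p = 0.891, 0.476 and 0.502). Of 186 named gene results, 177 kept their call with an offset of 8, 158 with the larger offset, 170 after quantile normalization, 162 without the mean trend and 182 with replicate number as a block. Fewer kept it when the arrays of a shared title were treated otherwise: 136 with all averaged, 130 with the second array only, 107 with the first only and 55 with every array as its own sample. In a fit on the compared mixes only, 82 of 134 kept it. Of 34 list results by camera, 21 kept their side after quantile normalization and 27 with the block. Where 1 sample of the compared mixes was left out in turn, 469 of 644 gene results kept their call. Lone NFull samples could not be left out, and a fit on the compared mixes only could not be run where each had 1 sample. A signal under the offset of 32, as in many E(spl) genes, in CG6067, TpnC4 and DptB in S2/S2 and in Oatp58Dc in S2-NFull/S2-Dl, shrinks a log2 change, so its size and rank depend on the offset.

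For S2/S2-Dl vs S2/S2 (245 calls), 382 were called with all arrays of a shared title averaged, 158 with every array as its own sample, 540 with the block, 77 in a fit on these mixes only and 373 with the upper part by mean signal, where fewer probe sets were tested. Leaving out S2/S2 replicate 1 gave 335, S2/S2-Dl replicate 1 gave 130 and replicate 2 gave 93. For S2/S2-DlDI vs S2/S2 (14), averaging gave 25, the first array only 7 and these mixes only 4, and leaving out DlDI replicate 2 or 3 gave 4 or 6. For S2/S2-Dl vs S2/S2-DlDI (120), every array gave 10, the first array only 62, the block 219, these mixes only 62 and the upper part by mean 190. Without S2/S2-Dl replicate 1, 2 or 3 there were 79, 67 or 123, and without DlDI replicate 2 or 3 there were 52 or 46.

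For S2-NFull/S2 vs S2/S2 (34), averaging gave 174, every array 292, the first array only 138, the second only 132, the block 53 and these mixes only 11. For S2/S2-NDCterm vs S2/S2 (31), averaging gave 85, every array 72, the second array only 62, the block 293 (143 higher, 150 lower), these mixes only 6 and no mean trend 19. Without S2/S2 replicate 3 there were 71, and without NDCterm replicate 1 or 3 there were 6 or 5. For S2-NDCterm/S2-Dl vs S2/S2-NDCterm (92), averaging gave 50, every array 0, the second array only 0, the block 234 and these mixes only 189. Leaving out a sample gave 35, 16, 19 or 26. The settings with 0 calls include array 2 of replicate 2, the array without Delta signal. Likewise, averaging, every array and the first array only place array 1 of S2-NFull/S2-DlDI replicates 1 and 3, with high Delta, in that mix. Every comparison is affected, because the mixes share a spread.

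For S2-NFull/S2-Dl against S2-NFull/S2 (55), averaging gave 131, every array 34 and the first array only 25. For S2-NFull/S2-DlDI against S2-NFull/S2 (4), averaging gave 17, every array 81, the first array only 19, the second only 25 and the block 9. For S2-NFull/S2-Dl against S2-NFull/S2-DlDI (40), averaging gave 5, the first array only 4, the second only 105 and the block 71.

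For the difference in the change with Delta between NFull and S2 (4 calls), every array gave 9, all higher and so none of the 4, the block 7, these mixes only 2 and the larger offset gave 1. For NDCterm and S2 (2 calls), quantile normalization, the larger offset, no mean trend, every array, the first array only, the block and these mixes only each gave 1, and leaving out a sample gave 1 to 4. For NFull with the 2 Delta forms (5 calls), averaging, the larger offset and these mixes only gave 0, the first array only 2 and no mean trend 3, and leaving out S2/S2-Dl replicate 1 or either DlDI replicate gave 3. For NFull against NDCterm (6 calls), averaging gave 3, the first array only 1, these mixes only 3 and the larger offset gave 2, and leaving out S2/S2-NDCterm or S2-NDCterm/S2-Dl samples gave 3 to 5.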

Other observations

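No test of an explanation was run in this part, and the probe sets given here were chosen after the values were seen. MtnA, a metallothionein that binds copper, differed between replicate numbers in some mixes and between mixes at the same number. Its signal was 8132, 5902 and 1192 in S2/S2 replicates 1 to 3 and 6273, 4167 and 1304 in S2/S2-Dl. In S2/S2-DlDI it was 3896 and 1034 for replicates 2 and 3, and in S2/S2-NDCterm 565 and 486 and in S2-NDCterm/S2-Dl 1083 and 921 for replicates 1 and 3. It was 1464 on both arrays of S2-NFull/S2-DlDI replicate 2. The array of S2/S2 replicate 2 had the highest median signal of the series (20.9) and a 10th percentile of 3.47.

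Among probe sets that name no gene, 1 had a mean signal of 3.72 in S2/S2 and 0.893 in S2-NFull/S2, against 1394 to 4185 in the 6 mixes with a Dl, DlDI or NDCterm line. Another stood at 122 in S2/S2 and 170.5 in S2/S2-Dl, against 2242 in S2-NFull/S2 and 2502 in S2/S2-NDCterm. The Imp probe set whose change with Delta cells differed in the NFull mix rose by 3.70 in S2/S2-Dl and by 3.72 in S2-NFull/S2, while the probe set that stands for Imp, which has the highest mean, was at -0.10 in S2/S2-Dl. A further Imp probe set rose by 1.67 and 1.85 in these mixes, and another was at -0.36 and -0.13.

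On the left-out arrays with a high Delta signal, array 1 of S2-NFull/S2-DlDI replicates 1 and 3, CG7900 was at 18.9 and 15.0, CG15784 at 274 and 407 and Oatp58Dc at 8.96 and 4.37. S2-NFull/S2-Dl replicate 2 had 17.3, 328 and 10.4. Array 1 of these replicates entered only the alternatives that use the arrays of a shared title.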
